A study of Danio rerio with 122 samples.

How the data were processed

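RNA of whole zebrafish embryos was measured on 61 Agilent arrays of 60 nt probes, on 15 slides of 4 arrays and 1 slide with a single array, in 13 groups of 4 or 5 arrays. Per the labels, 0.5 µg of total RNA with an integrity number above 7 was amplified and labelled with Cy3, and a common reference pooled from all samples was labelled with Cy5, with no exchange of dyes. Each array's 2 channels were listed as separate samples, 122 in all, and the files of the channels of an array were identical, so arrays were counted. Groups and replicate numbers came from the labels. Per the labels, injections were made in random order.

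The deposited scanner files hold spot intensity values on a linear scale, with 44787 spots per array, written by Agilent Feature Extraction 9.5.1.1 per the submitters' processing notes. Their processed signals, background-subtracted and dye-normalized intensities, are the scanner software's work per the file headers and served only as an alternative. The authors' deposited series matrix holds 1 column per channel on a log2 scale. Its medians lay between 11.50 and 11.53 for Cy3 and between 10.62 and 10.63 for Cy5, and its columns correlated with the log2 mean signal of the same spots at 0.995 or more. Its Cy3 maxima were equal on all arrays. The log ratios from its columns correlated with the scanner's log ratios at 0.20 to 0.40 across probes. Genes were not centred, the direction follows the named dyes, and the exact normalization is not given in the sources used here.

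Mean spot signals were corrected with the local background median by normexp with an offset of 50, and dyes were normalized within each array by loess, in limma 3.58.1 under R 4.3.3. The 1417 control spots and spots with an outlier mark had no weight in the loess. Values with an outlier mark, 0.052% of values in 743 tested probes, were left out. The measure was log2 of sample Cy3 over reference Cy5. A probe was tested if its sample channel was well above background on 4 or more arrays, which kept 27194 of 43370 probes and left out 16176. With no exchange of dyes, a probe's level against the reference is open to dye bias, which cancels in differences between groups.

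The design planned 1 value per gene, taken from the brightest probe. The files pair 0 probes with a gene name, so each probe was tested by itself. Gene list tests and traf6 transcript were not analysed here. Named probes follow the planned rule as far as it can be applied without gene names, being the first 2 each way by size in both traf6 morpholinos against both controls at 2 mM. They had to be called, with all 10 arrays of the arm on 1 side of the control mean, which 1885 higher and 828 lower probes met. Since they were chosen by size at 2 mM, their sizes and p values in contrasts that use those arrays may be inflated.

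Group means were fitted to all 61 arrays with lmFit and eBayes, so that the groups share an estimate of the spread, and contrasts were called at a Benjamini-Hochberg adjusted p under 0.05. The 20 comparisons, the agreement counts at 3 doses, the naming rule and most alternatives were chosen before the data were examined. Single values were compared by two-sided exact permutation tests. Where no array of a group measured a probe well above background, the fold is a bound. The bright group's mean Cy3 level after loess and quantile normalization of the channels was set against, per array, the higher of the probe's own level and the lowest level of any probe well above background. For comparisons that share phenol red arrays, 100 unchanged pairs of groups with a shared control were simulated. Groups and control were drawn from the residuals of all 61 arrays, not from phenol red alone. The phenol red arrays were also divided between the comparisons in 10 ways.

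Pairing by replicate number was checked with the correlation of deviations from group means. The labels state 5 replicates and no shared litter or day. Every same-numbered pair correlated over 0.1 in 5 comparisons. These were morpholino 2 against the standard control at 0.5 mM (0.196 to 0.330), both morpholinos against both controls at 0.5 mM (0.171 to 0.564) and 1 mM (0.399 to 0.617), morpholino 1 against morpholino 2 at 2 mM (0.165 to 0.609) and morpholino 2 between doses (0.213 to 0.342). In these the numbers were taken to pair the arrays, as read from the data. The counts, SE and p values reported for these 5 still come from the fit without pairing, with the replicate block as an alternative.

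Each slide was scanned by itself, so slide and scan are the same batch. Slides held several groups, and the slide was fitted as a fixed block, which takes the single array of slide 16 (morpholino 2 at 2 mM replicate 1) out of the comparisons. Probes called without a slide's arrays were then read within that slide. Slides accounted for 94.7% of the variance of the median Cy3 background, which ranged from 366 to 1272, and median Cy3 signal over background ranged from 3.04 to 6.02. Cy5 spots well above background made up 67.1% to 87.0% of an array.

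The alternatives were the processed signals, quantile normalization between arrays, the sample channel alone, no filter on dim probes, the slide and the replicate number as blocks, only the compared arrays in the fit, the series matrix and leaving out each array in turn. Quantile normalization of average intensity leaves log ratios as they are, so its counts are equal by construction. After the data were seen, 5 more were added. These were probes sharing a stretch of 25 nt reduced to the brightest, 2 arrays that stood apart left out, log ratios scaled between arrays, the slide as a random block and phenol red in place of the control oligonucleotides.

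The fit was tested on simulated data with independent noise at the real spread of each probe. These data lack the correlation of real arrays within slides and replicate numbers, so their rates of false calls need not hold for the real arrays. With no change it made 0 calls with limma in all 23 results. Of 200 probes per size on 27194, it recovered 26.5%, 72.0%, 93.5% and 99.0% of changes of 1.25, 1.5, 2 and 3-fold in both morpholinos against both controls at 2 mM, with 3.0% false calls. For morpholino 1 against the mismatch at 2 mM it recovered 7.0%, 41.5%, 81.5% and 95.0%, with 3.64% false, and for the dose interaction 8.0%, 40.5%, 78.5% and 95.0%, with 5.73% false. A 2-fold change set in the scanner signals of 200 probes came back as 2.27-fold at the median (2.15 to 2.51), and the cause of the excess was not tested. No pair of the 114 pairs of arrays within groups was a repeat, with a highest correlation of 0.754.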

Results

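Zebrafish embryos received a single injection and were collected at 30% epiboly, a blastula stage at which the cell layer has begun to spread over the yolk. The labels conflict on the stage of injection, which is the 1-cell stage in the treatment protocol and 30% epiboly in the sample descriptions. The question named by the series was the role of traf6 in early development. Traf6 is a ubiquitin ligase and adaptor protein that relays signals from Toll-like and interleukin receptors. Morpholinos are synthetic antisense oligonucleotides, and both traf6 morpholinos, which bind sites in the 5' untranslated region that do not overlap, were designed to block translation. A morpholino with a 5 bp mismatch to morpholino 1, a standard control morpholino and buffer with phenol red served as controls. Each oligonucleotide was injected at 0.5, 1 and 2 mM.

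Transcript levels were measured on 61 two-colour arrays in 13 groups, each array carrying 1 sample in Cy3 and a pooled reference in Cy5. Phenol red was measured on 5 arrays and the standard control on 5 arrays per dose. The mismatch oligonucleotide had 4, 4 and 5 arrays at 0.5, 1 and 2 mM, and each traf6 morpholino had 4, 5 and 5. Between 44.9% and 65.0% of the spots of an array were well above background in the sample channel, and 27194 of 43370 probes were tested. The number of arrays limits the precision of every value. The files do not pair the probes with genes, so probes are named by their identifiers, and traf6 transcript was not analysed here. Because the labels do not state separate clutches, p-values measure only the spread between these samples, which may be technical.

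At 2 mM, 5980 probes differed between the arms that received a traf6 morpholino and the arms that received a control oligonucleotide, 3504 of them higher and 2476 lower. Probe LOLS13524 was higher (adjusted p 1.79e-12), and no fold is given because it was not well above background on any of the 5 standard control arrays at 2 mM. Against phenol red its rise was 0.76 and 0.85 on the log2 scale for morpholinos 1 and 2. LOLS06789 rose 3.78-fold (log2 1.92, SE 0.18, 10 against 10 arrays, adjusted p 4.23e-12), and against phenol red by 1.07 (SE 0.22, adjusted p 0.000181), since the standard control lay below phenol red. LOLS10447 fell by 2.00 on the log2 scale (SE 0.21, adjusted p 9.97e-11) and A_15_P112621 fell by 1.73 (SE 0.18, adjusted p 1.82e-10).

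The 4 probes are 60 nt long and their place in the genome was not used here. LOLS13524 has the sequence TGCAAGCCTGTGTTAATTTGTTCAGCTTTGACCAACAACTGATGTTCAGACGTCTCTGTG and LOLS06789 has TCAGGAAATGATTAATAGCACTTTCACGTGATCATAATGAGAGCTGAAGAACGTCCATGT. LOLS10447 has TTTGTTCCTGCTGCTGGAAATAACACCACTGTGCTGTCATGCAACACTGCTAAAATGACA and A_15_P112621 has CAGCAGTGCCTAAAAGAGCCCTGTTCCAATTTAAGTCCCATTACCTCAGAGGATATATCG. Not every array measured them well above background. LOLS13524 passed in 0 of 5 standard control arrays and 3 of 5 mismatch arrays at 2 mM, and LOLS10447 in 1 of 5 morpholino 1 and 2 of 5 morpholino 2 arrays. A_15_P112621 passed in 3 of 5 morpholino 2 arrays, and LOLS06789 in 4 of 5 standard control arrays.

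The median size of the 5980 differences was 0.45 on the log2 scale, and 175 probes were higher and 75 lower by 1 or more. Probes were also called with the morpholino arrays of 3 replicate numbers and read against phenol red in those of the other 2, so that no array served in both. Over the 10 such divisions, a test added after the data were seen, 92.2% of the probes had the same sign on average (87.3% to 96.1%). The test was the moderated test of limma on all 61 arrays. With the slide as a block 7465 probes were called, and on slide 9, the only slide with all 4 groups, 74.3% of the probes called without its arrays had the same direction.

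**Figure D1:**
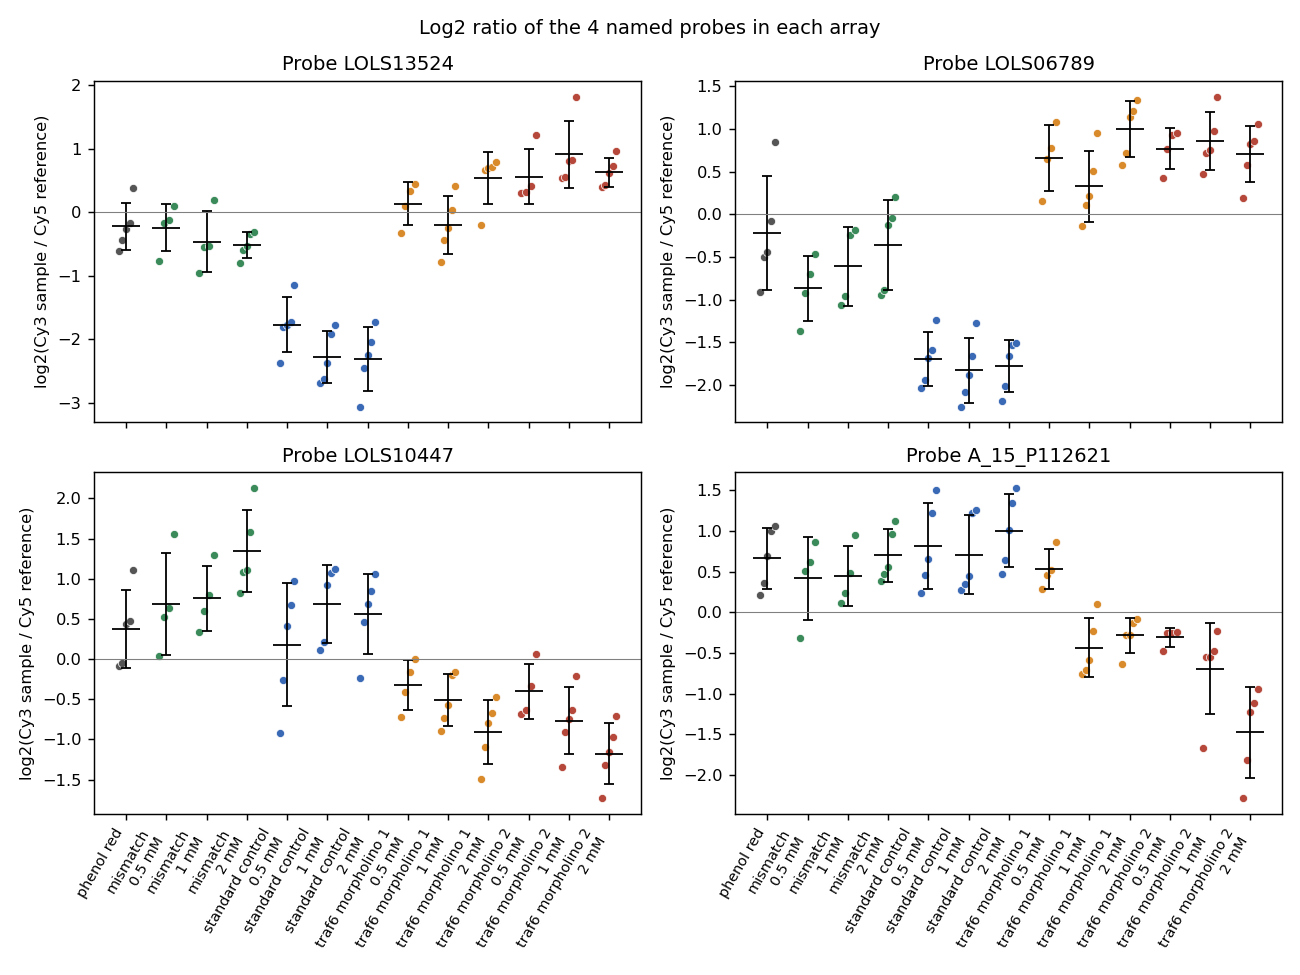
Log2 ratio of sample (Cy3) to reference (Cy5) on the vertical axis for the 4 named probes, with the 13 groups on the horizontal axis, a point per array, and bars for the mean ± SD of 4 or 5 arrays. The standard control groups have the lowest means for LOLS13524 (-1.77, -2.28 and -2.31, with 1, 0 and 0 of 5 arrays well above background, against -0.22 in phenol red) and LOLS06789, and traf6 morpholino 2 at 2 mM has the lowest mean for A_15_P112621 (-1.48).

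Against phenol red, which carries the injection itself but no oligonucleotide, both traf6 morpholinos changed many probes at 2 mM. Morpholino 2 altered 9037 probes (5028 higher, 4009 lower) and morpholino 1 altered 2406 (1579 higher, 827 lower). LOLS13524 was higher by 0.76 with morpholino 1 (SE 0.25, adjusted p 0.0473) and by 0.85 with morpholino 2 (SE 0.25, adjusted p 0.00695), 5 against 5 arrays. LOLS06789 was higher by 1.21 (SE 0.25, adjusted p 0.000603) and by 0.92 (SE 0.25, adjusted p 0.00332). LOLS10447 fell by 1.29 (SE 0.29, adjusted p 0.00195) and by 1.56 (SE 0.29, adjusted p 3.33e-05) with morpholinos 1 and 2. A_15_P112621 fell by 0.95 (SE 0.26, adjusted p 0.0118) with morpholino 1 and by 2.14 (SE 0.26, adjusted p 3.85e-09) with morpholino 2. With the slide as a block, limma called 3064 probes for morpholino 1 and 9322 for morpholino 2, and with only the compared arrays in the fit 746 and 5828. Within slide 13, 79.9% of the calls for morpholino 1 kept their direction, and within slide 7, 93.7% of those for morpholino 2.

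The control oligonucleotides at 2 mM changed fewer probes against phenol red. The standard control altered 474 probes, 155 higher and 319 lower, with a median size of 0.67 on the log2 scale. LOLS13524 was at least 3.08-fold lower with the standard control than with phenol red, a bound because no standard control array measured it well above background (adjusted p 5.98e-08). LOLS06789 fell by 1.56 (SE 0.25, adjusted p 3.72e-05). The count became 816 without phenol red replicate 3, with 415 higher and 401 lower, so that the excess of lower over higher probes was not stable. It was 289 without standard control replicate 3, 738 with the slide as a block and 97 (12 higher, 85 lower) with only the compared arrays in the fit. On slides 7, 13 and 15, 94.2%, 83.9% and 94.0% of the calls kept their direction.

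The mismatch oligonucleotide altered 283 probes against phenol red, 107 higher and 176 lower. None of the 4 named probes was among them: LOLS10447 differed by 0.97 (SE 0.29, adjusted p 0.087) and LOLS13524 by -0.29 (SE 0.25, adjusted p 0.665). This count rests on single arrays, being 494 without phenol red replicate 5 and 127 without mismatch replicate 4. Of 100 splits of the 10 arrays, the real one included, 11 called as many probes or more. With the slide as a block 134 were called, with only the compared arrays in the fit 10 and with scaled log ratios 59, and on slide 7 the direction held for 83.5%.

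Changes of the control oligonucleotides against phenol red were compared with each other. Only 22 probes were called alike by both, 12 higher and 10 lower, where independent lists would share 2.67, and 0 were called in opposite directions by limma. Both lists use the same phenol red arrays, which can by itself raise the number called alike and lower the number called opposite. The log2 changes correlated at r = 0.530 across probes, which are not independent replicates. Simulated unchanged groups with a shared control gave a mean r of 0.536 (-0.039 to 0.833 over 100 simulations). The covariance was 0.0449, against a mean of 0.0293 in the simulations (up to 0.0701), whose controls were not the phenol red arrays themselves. With the phenol red arrays divided between the comparisons the mean r over 10 divisions was 0.00373, with a covariance of -0.00077.

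The same comparison for the traf6 morpholinos gave 1680 probes called alike against phenol red, 1218 higher and 462 lower. Independent lists would share 413.9, and 68 probes were called in opposite directions. These lists are not independent, since the shared phenol red arrays can raise the number called alike and lower the number called opposite. The correlation across probes was 0.586, which lay within the range of the simulations of unchanged groups (mean 0.490, 0.0113 to 0.778). It was 0.271 with the phenol red arrays divided. The covariance was 0.108, against a mean of 0.0265 in the simulations (up to 0.0708) and 0.0627 with divided controls.

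**Figure D2:**
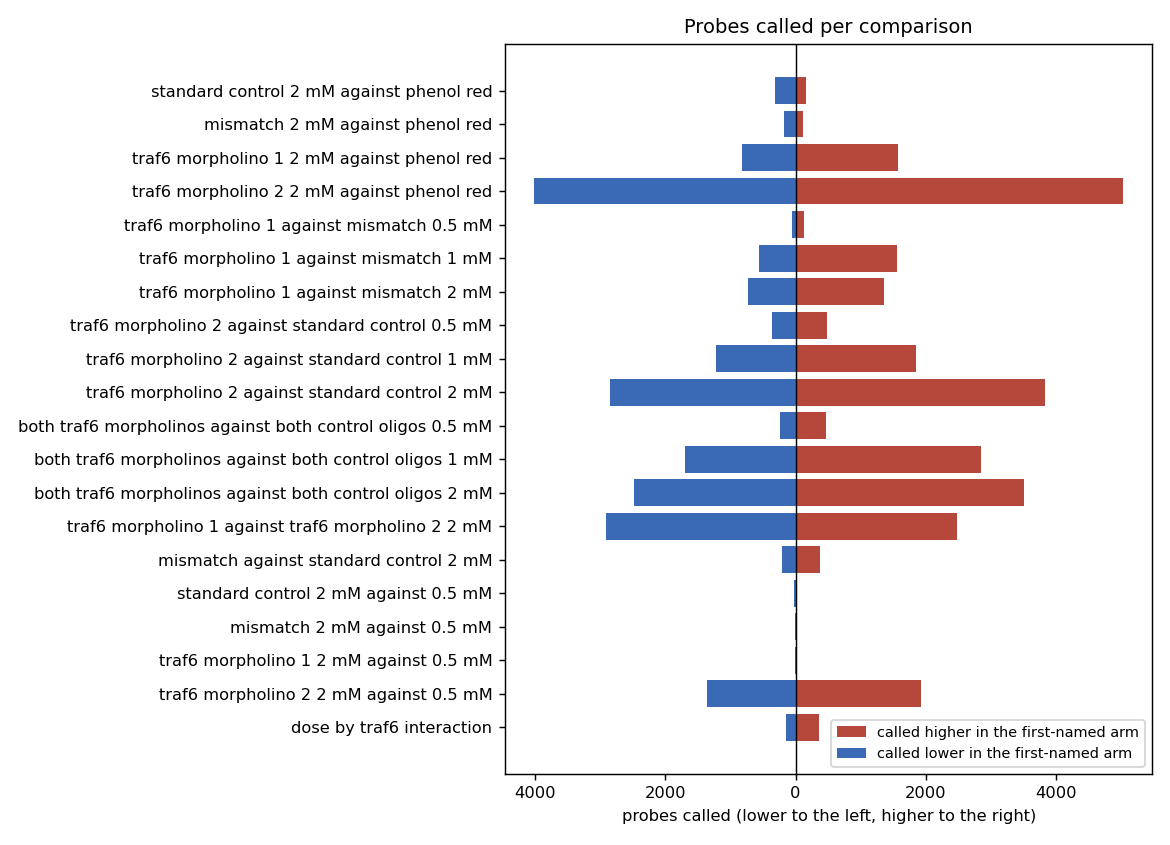
Number of probes called higher (right) and lower (left) in the first-named arm on the horizontal axis, with 1 bar per comparison on the vertical axis, from 27194 probes tested with limma. Bars of morpholino 2 at 2 mM are the longest (5028 higher and 4009 lower against phenol red), and changes of dose within the standard control, mismatch and morpholino 1 arms stay under 30 probes.

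Morpholino 1 was set against its mismatch control at each dose. It altered 183 probes at 0.5 mM (135 higher, 48 lower), 2112 at 1 mM (1555 higher, 557 lower) and 2087 at 2 mM (1353 higher, 734 lower). LOLS10447 fell by 2.26 at 2 mM (SE 0.29, 5 against 5 arrays, adjusted p 2.78e-07) and by 1.27 at 1 mM (SE 0.31, adjusted p 0.0053). LOLS06789 was higher at all 3 doses, by 1.53 (SE 0.28, adjusted p 0.00106), 0.94 (SE 0.27, adjusted p 0.0181) and 1.36 (SE 0.25, adjusted p 0.000187). LOLS13524 rose by 1.05 at 2 mM (SE 0.25, adjusted p 0.00432), while its differences at 0.5 and 1 mM were 0.38 (SE 0.28) and 0.26 (SE 0.27).

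Single arrays moved the smaller of these counts. At 0.5 mM limma called 105 and 88 probes without mismatch replicates 2 and 4, and 94, 104 and 104 without morpholino 1 replicates 1, 4 and 5. At 1 mM the counts were 1352 and 1126 without mismatch replicates 1 and 2. With the slide as a block the counts were 270, 2902 and 3023, and with only the compared arrays in the fit 32, 2175 and 701. Directions held within slides 5 and 10 for 89.2% and 100% of the calls at 0.5 mM, within slides 2 and 14 for 98.4% and 95.7% at 1 mM, and within slides 1 and 9 for 98.2% and 73.3% at 2 mM.

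Morpholino 2, whose control was the standard oligonucleotide, changed 843 probes at 0.5 mM (483 higher, 360 lower), 3075 at 1 mM (1856 higher, 1219 lower) and 6667 at 2 mM (3824 higher, 2843 lower). LOLS13524 was at least 6.51-fold higher at 1 mM (adjusted p 6.91e-14) and at least 5.14-fold higher at 2 mM (adjusted p 2.7e-13), bounds set by standard control arrays that did not measure it well above background. LOLS06789 rose by 2.47 (SE 0.27), 2.69 (SE 0.25) and 2.48 (SE 0.25) at 0.5, 1 and 2 mM. The change of A_15_P112621 was -1.12 (SE 0.28, adjusted p 0.0105), -1.40 (SE 0.26, adjusted p 9.74e-05) and -2.48 (SE 0.26, adjusted p 1.1e-10). For LOLS13524 and LOLS06789 the standard control itself lay below phenol red, so these sizes hold both departures.

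At 0.5 mM the replicate numbers paired the arrays, and 1539 probes were called with the replicate block. Without morpholino 2 replicates 1 and 2 the count at 0.5 mM was 556 and 539. The slide block gave 534, 3620 and 7575 probes at the 3 doses, with 261 higher and 273 lower at 0.5 mM, so the excess of higher probes at that dose was not stable. With only the compared arrays in the fit the counts were 140, 2838 and 6180. No slide held both arms at 0.5 mM, while the direction held for 95.3% of the calls within slide 6 at 1 mM, and for 98% and 90.2% within slides 7 and 9 at 2 mM.

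With both morpholinos against both controls, 703 probes were called at 0.5 mM (464 higher, 239 lower) and 4545 at 1 mM (2847 higher, 1698 lower). LOLS06789 rose by 2.00 (SE 0.19, adjusted p 2.5e-10) and by 1.81 (SE 0.18, adjusted p 1.28e-10) at these doses. LOLS10447 fell by 0.79 (SE 0.23, adjusted p 0.0424) and by 1.36 (SE 0.21, adjusted p 3.52e-06). A_15_P112621 differed by -0.50 at 0.5 mM (SE 0.20, adjusted p 0.192) and fell by 1.14 at 1 mM (SE 0.19, adjusted p 9.42e-06). The replicate numbers paired the arrays at both doses, and the block moved the count at 0.5 mM to 1528. That count was 399 without morpholino 1 replicate 5 and 403 and 433 without morpholino 2 replicates 1 and 2. With the slide as a block limma called 253 and 6275 probes. With only the compared arrays in the fit it called 270 higher and 90 lower at 0.5 mM, and 3262 higher and 2282 lower at 1 mM. No slide held all 4 groups at either dose.

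Probes called in the same direction by both traf6 morpholinos, each against its own control with no array in common, numbered 27 at 0.5 mM, 761 at 1 mM and 900 at 2 mM. At 2 mM these were 721 higher and 179 lower, where independent lists would share 190.3 and 76.7. A further 210 probes were called in opposite directions at 2 mM, against 244.7 from independent lists, and 62 at 1 mM, against 107.7. Odds ratios of Fisher's exact test across probes, which are not independent, were 8.36 for higher and 2.88 for lower probes at 2 mM. Across all probes the effects of the morpholinos correlated at r = 0.219, 0.363 and 0.211 at 0.5, 1 and 2 mM. The count at 1 mM was 499 without mismatch replicate 2. With only the compared arrays in the fit the counts were 7, 668 and 280 at 0.5, 1 and 2 mM, so the order of the 1 and 2 mM counts depends on that setting.

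The traf6 morpholinos differed from each other at 2 mM in 5383 probes, 2480 higher and 2903 lower with morpholino 1. A_15_P112621 was higher with morpholino 1 by 1.19 (SE 0.26, 5 against 5 arrays, adjusted p 0.000524). LOLS13524, LOLS06789 and LOLS10447 differed by -0.09 (SE 0.25), 0.29 (SE 0.25) and 0.27 (SE 0.29), with adjusted p of 0.852, 0.47 and 0.591. With the slide as a block 5555 probes were called, and 97.0% and 98.6% kept their direction within slides 4 and 9.

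The control oligonucleotides differed from each other at 2 mM in 584 probes, 370 higher and 214 lower with the mismatch oligonucleotide. LOLS13524 was at least 2.48-fold higher with the mismatch (adjusted p 2.55e-06) and LOLS06789 was higher by 1.42 (SE 0.25, adjusted p 0.000215). LOLS10447 and A_15_P112621 differed by 0.78 (SE 0.29, adjusted p 0.191) and -0.30 (SE 0.26, adjusted p 0.703). The slide block gave 706 probes and the compared arrays alone gave 183 (131 higher, 52 lower), and 98.7% and 95.9% of the calls held their direction within slides 7 and 9.

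Raising the dose from 0.5 to 2 mM changed 3288 probes within the morpholino 2 arm, 1923 higher and 1365 lower. A_15_P112621 fell by 1.17 (SE 0.28, adjusted p 0.00264), and LOLS10447 differed by -0.78 (SE 0.31, adjusted p 0.0959). Both probes were chosen for their large fall at 2 mM, which favours a fall with dose. Within the standard control arm 29 probes changed (2 higher, 27 lower), within the mismatch arm 14 (6 higher, 8 lower) and within the morpholino 1 arm 5 (4 higher, 1 lower). With only the compared arrays in the fit limma called 1288 higher and 766 lower probes within the morpholino 2 arm. In the other 3 arms that fit called 0, 0 and 0, with 1402, 2299 and 1340 at an unadjusted p under 0.05. None of the 4 named probes was called in those 3 arms. In the test of the difference itself, chosen after the counts were seen, the dose effects of the morpholinos differed in 68 probes.

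For morpholino 2 the dose count was 1494 without replicate 4 at 0.5 mM and 1980 without replicate 3 at 2 mM. For the standard control it was 17 and 9 without replicates 3 and 5 at 0.5 mM, and 11, 12 and 18 without replicates 3, 4 and 5 at 2 mM. For the mismatch it was 32, 2, 0 and 2 without replicates 1, 2, 4 and 5 at 0.5 mM and 95, 8, 0 and 0 without replicates 1, 2, 4 and 5 at 2 mM. The 3 counts of 0 came with 2015, 2268 and 2806 probes at an unadjusted limma p under 0.05. For morpholino 1 it was 0 and 0 without replicates 1 and 2 at 0.5 mM, with 1441 and 933 unadjusted. Slide blocks gave 3601, 11, 15 and 2 probes for morpholino 2, standard control, mismatch and morpholino 1. Within slides the direction held for 91.5% and 95.2% of the calls of morpholino 2 (slides 4 and 11), 93.6% of those of the standard control (slide 3) and 62.5%, 100% and 100% of those of the mismatch (slides 1, 5 and 12). No slide held both doses of morpholino 1.

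Probes called at 1 mM were then read at the other doses. For morpholino 1, 94.9% of its 2112 probes had the same sign at 0.5 mM and 97.1% at 2 mM. For morpholino 2 the shares of its 3075 probes were 94.0% and 99.6%. A score per array, the mean of the medians of the higher probes and of the lower probes with their sign turned, lay 0.28 above the mismatch at 0.5 mM and 0.40 above it at 2 mM for morpholino 1, with exact permutation p of 0.0286 and 0.00794. For morpholino 2 the score lay 0.33 and 0.71 above the standard control, both with an exact permutation p of 0.00794. The score was higher at 2 mM than at 0.5 mM by 0.22 for morpholino 1 and 0.38 for morpholino 2, with exact p of 0.0159 and 0.00794. The mismatch score also moved between these doses, from -0.24 to -0.14, and the standard control score went from -0.17 to -0.18. Whether the morpholinos rose by more than their controls was not tested with this score. After adjustment over these 6 two-sided tests the p values lay between 0.0119 and 0.0286.

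The effect of traf6 morpholinos against controls differed between 0.5 and 2 mM in 509 probes. The 2 mM effect minus the 0.5 mM effect was positive in 360 of them and negative in 149. This sign is a direction and not a size, since a stronger fall at 2 mM also gives a negative value. LOLS10447 and A_15_P112621 were among the 509, with differences of -1.21 (SE 0.31, adjusted p 0.0242) and -1.23 (SE 0.27, adjusted p 0.00909). Both were chosen for their large fall at 2 mM, which favours such a difference, so these p values are not an independent test. LOLS13524 (adjusted p 0.229) and LOLS06789 (-0.08, SE 0.26, adjusted p 0.936) were not. The count was 333 without mismatch replicate 2 at 2 mM, 321 without morpholino 1 replicate 2 at 0.5 mM and 332 without morpholino 2 replicate 4 at 0.5 mM. The slide block gave 1252, while only the compared arrays in the fit gave 202 with a positive and 72 with a negative difference. No slide held every group.

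A response score, the median of the probes called higher at 2 mM minus the median of those called lower, was read in each array after centring every probe on its mean. Arrays at 2 mM were scored with calls made without their replicate number. Phenol red scored -0.33 ± 0.11 (SD, n = 5), and the control oligonucleotide groups had means between -0.38 and -0.23. Morpholino 1 scored -0.01 ± 0.13 (n = 4), 0.28 ± 0.09 (n = 5) and 0.25 ± 0.17 (n = 5) at 0.5, 1 and 2 mM, and morpholino 2 scored 0.10 ± 0.19 (n = 4), 0.45 ± 0.12 (n = 5) and 0.89 ± 0.17 (n = 5).

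At 1 mM all 5 arrays of morpholino 1 scored above its control's arrays, as did all 5 of morpholino 2, each with a two-sided exact permutation p of 0.00794 and 0.0476 after adjustment over 12 tests. At 0.5 mM the exact p was 0.0286 for morpholino 1, the smallest that 4 against 4 arrays allow, and 0.0397 for morpholino 2, or 0.0686 and 0.0794 after adjustment. Scores of control groups at 0.5 and 1 mM differed from phenol red by less than the spread between arrays, with exact p between 0.254 and 0.746.

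**Figure D3:**
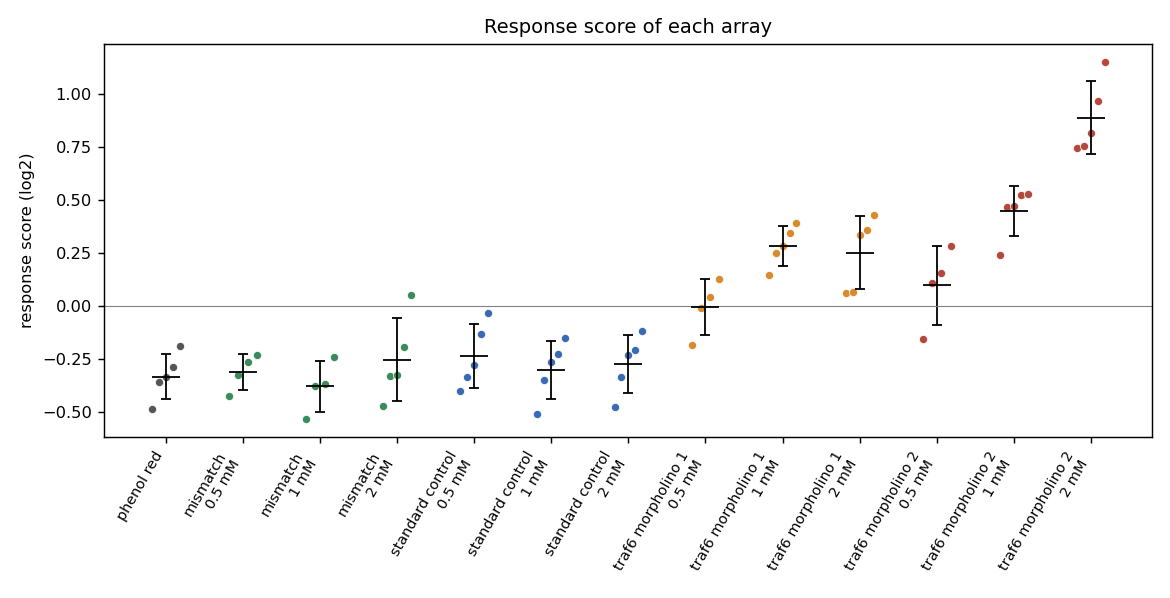
Response score (log2) of each array on the vertical axis, with the 13 groups on the horizontal axis, a point per array and bars for the mean ± SD of 4 or 5 arrays. Control groups lie between -0.38 and -0.23 on average, and morpholino 2 lies at 0.10, 0.45 and 0.89 at 0.5, 1 and 2 mM.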

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

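The tests of the slide and the control arms for the larger response to morpholino 2, the test of shared handling for phenol red replicate 5, and the tests behind 3152 and 68 probes were chosen only after the results they bear on were seen.

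Across 13 groups and 7 measures, 8 of 91 tests had an array far from the rest of its group by Dixon's criterion, where chance gives about 1 in 20. For LOLS13524, traf6 morpholino 1 at 2 mM replicate 2 read -0.20 on the log2 scale while the others read 0.67 to 0.80. Morpholino 2 at 0.5 mM replicate 1 read 1.21 (others 0.31 to 0.41), and morpholino 2 at 1 mM replicate 5 read 1.82 (others 0.54 to 0.82). For A_15_P112621, morpholino 2 at 0.5 mM replicate 4 read -0.48 (others -0.26 to -0.25), and morpholino 2 at 1 mM replicate 2 read -1.67 (others -0.55 to -0.23). The response score of morpholino 2 at 1 mM replicate 4 was 0.24 (others 0.47 to 0.53). In SD of the difference from the rest of its group over all probes, morpholino 2 at 0.5 mM replicate 4 stood at 0.448 (others 0.341 to 0.351).

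The effect of traf6 morpholinos against controls differed between doses in 509 probes by the interaction test. The dose effects of morpholino 1 and morpholino 2 differed from each other in 68 probes. The morpholino 2 effect minus the morpholino 1 effect was above zero in 25 of them and below zero in 43. This sign is a direction and not a size, since a stronger fall with morpholino 2 also gives a value below zero.

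The effects of the traf6 morpholinos against their own controls at 2 mM differed from each other in 3152 probes, and against phenol red morpholino 2 changed 9037 probes and morpholino 1 changed 2406. For morpholino 1 set directly against morpholino 2 the values argue against the slide. There 97.0% and 98.6% of the probes called without the arrays of slides 4 and 9 kept their direction within them. The shares were 98.2% and 73.3% for morpholino 1 against mismatch (slides 1 and 9). They were 98% and 90.2% for morpholino 2 against the standard control (slides 7 and 9). Against phenol red they were 79.9% for morpholino 1 (slide 13) and 93.7% for morpholino 2 (slide 7). For the 3152 probes and the counts against phenol red the slide stays open. The different control arms do not enter the counts against phenol red or the 5383 probes that differed between the morpholinos directly. They can be behind part of the 3152 probes. LOLS06789 is one of these (limma, adjusted p 0.0289). Its mean log2 ratios at 2 mM were 1.00 and 0.70 with morpholinos 1 and 2, and -0.36 and -1.78 with their controls. Compression of dim probes by background is also unlikely as the whole cause, because among the 3703 bright probes also called in both morpholinos against both controls at 1 mM, read in that direction, the morpholino 2 effect exceeded the morpholino 1 effect by 0.36 at the median (0.32 to 0.39 leaving out 1 array). That excess may be inflated, since morpholino 2 had more calls at 1 mM (3075 against 2112) and the choice of probes may favour it. Whether one response differs only in strength stays open: of the 3152 probes, 61.8% had the morpholino 2 direction with morpholino 1 at 1 mM, and 210 were called in opposite directions at 2 mM. A stronger block of traf6 by morpholino 2, or an effect of its sequence apart from traf6, may each account for the pattern, and the design holds no mismatch of morpholino 2 to part them.

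Phenol red replicate 5 stood 0.832 from the rest of its group in SD of the difference over all probes, where the other phenol red arrays stood at 0.38 to 0.45. Whether its label is wrong stays open, since the array lay far from every group, its own included, and its distances cannot place it. The smallest was 0.767, to the mean of morpholino 1 at 0.5 mM, less than to phenol red. No array of that morpholino 1 group lay further than 0.434 from it. The response score of phenol red replicate 5 was -0.335, within the phenol red range of -0.486 to -0.190. That morpholino 1 group read -0.185 to 0.128, which argues against its label for this array. The response score does not part phenol red from the control oligonucleotides. On a score of probes that differed between those at 1 mM, mismatch arrays read -0.192 at most and standard control arrays 0.143 at least. There the array read -0.093 (other phenol red arrays -0.194 to -0.105). Slide and shared handling of replicate 5 both stay open, since its deviations correlated with those of its 3 slide mates, all replicate 5, at a mean r of 0.183 and with the 12 replicate 5 arrays of other groups at 0.116. The 9 of these on other slides had a mean r of 0.0934 (-0.119 to 0.359), and arrays of other numbers -0.0372. No biological explanation was tested.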

How the results depend on the processing

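The alternatives with overlapping probes reduced, 2 arrays left out, scaled log ratios, the slide as a random block and phenol red as the control were chosen only after the data were seen. Over 23 results and their alternatives, 475 of 579 counts stayed within 1.5 times the reported count and 104 moved further. Of the 579, 302 came from leaving out 1 array, of which 265 stayed within. The replicate block and the compared arrays alone each kept 7 of 23 counts within, and the slide as a random block 15 of 23. The 4 named probes kept direction and call in all 308 of their tests, but not their size. They were chosen for large changes on the same arrays, which favours this outcome. For both morpholinos at 2 mM LOLS10447 was at -0.94 from the series matrix and -2.84 from processed signals (reported as a fall by 2.00), A_15_P112621 at -1.01 from the series matrix (reported -1.73) and LOLS06789 at 1.07 with phenol red as the control (reported 1.92). For morpholino 2 at 2 mM the series matrix gave 1.57 for LOLS06789, -1.36 for A_15_P112621 and -0.70 for LOLS10447 (2.48, -2.48 and -1.74 in the reported fit), and for morpholino 1 it gave -1.17 for LOLS10447 (reported -2.26). The bounds for LOLS13524 were computed in the reported processing only and need not hold in the alternatives. Quantile normalization between arrays (equal by construction), overlapping probes reduced to the brightest (24693 probes) and phenol red as the control (6509 for both morpholinos against both controls at 2 mM) moved no count by over 1.5 times. Counts of morpholino 2 against the standard control at 1 and 2 mM, of both morpholinos at 1 and 2 mM and of morpholino 1 against morpholino 2 stayed within 1.5 times in every alternative and with each array left out. Except where said, the cause was not tested.

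Agilent's processed signals gave 36 probes for the mismatch between doses and 10 for morpholino 1 between doses. The sample channel alone gave 16 for the standard control and 10 for morpholino 1 between doses. Without the filter on dim probes, with more probes tested, the counts were 162 (mismatch against phenol red), 118 (morpholino 1 against mismatch, 0.5 mM), 418 (both morpholinos, 0.5 mM) and 1 (mismatch between doses). Series matrix values gave 292 for the standard control against phenol red, 7 for the mismatch between doses and 9 for morpholino 1 between doses.

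The slide as a fixed block gave 738 and 134 for the standard control and mismatch against phenol red, 534 for morpholino 2 against the standard control at 0.5 mM, 253 for both morpholinos at 0.5 mM, 11 and 2 for the standard control and morpholino 1 between doses, and 1252 for the interaction. As a random block, with a correlation of 0.268 within slides, it gave 1101 and 447 against phenol red, 380 and 3197 for morpholino 1 against mismatch at 0.5 and 2 mM, 927 for mismatch against standard control, 98 and 10 for the mismatch and morpholino 1 between doses, and 1364 for the interaction.

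The replicate block raised most counts. Against phenol red it gave 1013 (standard control), 934 (mismatch) and 3764 (morpholino 1). It gave 464, 3186 and 3258 for morpholino 1 against mismatch at 0.5, 1 and 2 mM, 1539 for morpholino 2 against the standard control at 0.5 mM, 1528 for both morpholinos at 0.5 mM and 1093 for mismatch against standard control. Between doses it gave 84 (standard control), 106 (mismatch) and 12 (morpholino 1), with 1397 for the interaction and 57, 1202 and 1412 probes called alike at 0.5, 1 and 2 mM. It moved no other count by over 1.5 times. Outside the 5 comparisons in which every same-numbered pair had r over 0.1, the labels give the arrays no more than a shared number. The data hold a hint of more in the standard control against phenol red, where all 5 arrays of the arm correlated best with their own number (mean r 0.316, other numbers -0.0771, lowest pair 0.0989), and in the interaction, where 92 of 122 pairs had r over 0.1 (mean 0.247, other pairs -0.063). In the other comparisons outside the 5, some arrays of the arm correlated best with another number.

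With only the compared arrays in the fit, hence fewer arrays behind the spread, the counts against phenol red were 97, 10, 746 and 5828 for standard control, mismatch, morpholino 1 and morpholino 2. They were 32 and 701 for morpholino 1 against mismatch at 0.5 and 2 mM, 140 for morpholino 2 against the standard control and 360 for both morpholinos at 0.5 mM, 183 for mismatch against standard control, 274 for the interaction, and 7 and 280 called alike at 0.5 and 2 mM. Between doses limma gave 0, 0, 0 and 2054 for standard control, mismatch, morpholino 1 and morpholino 2, the first with 1402, 2299 and 1340 at an unadjusted p under 0.05.

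Without phenol red replicate 5 and standard control 0.5 mM replicate 5, the counts were 684 for mismatch against phenol red, and 13 and 71 for the standard control and mismatch between doses. Scaled log ratios gave 59 for mismatch against phenol red, 98 and 1973 at 0.5 mM for morpholino 1 against mismatch and morpholino 2 against the standard control, 322 for the interaction, and 0 and 0 in limma for mismatch and morpholino 1 between doses (2222 and 1391 unadjusted). Among counts of 20 or more, the split of higher and lower calls moved by over 10 points for the standard control against phenol red (62 and 230 from the series matrix, 12 and 85 with only the compared arrays, 517 and 584 with the random slide block, 415 and 401 without phenol red replicate 3), mismatch against phenol red (54 and 152 from the sample channel, 346 and 338 without the 2 arrays, 243 and 251 without phenol red replicate 5) and morpholino 1 against mismatch at 0.5 mM (29 and 3 with only the compared arrays). The majority also turned for morpholino 2 against the standard control at 0.5 mM (261 and 273 with the fixed slide block) and for the mismatch between doses (36 and 35 without the 2 arrays). Smaller counts moved too. The mismatch between doses had 1 and 0 without the filter, 4 and 11 with the fixed slide block, 2 and 5 from the series matrix, and 0 and 2 and 1 and 7 without replicate 2 at 0.5 and 2 mM. Morpholino 1 between doses had 5 and 5 from processed signals, 6 and 4 from the sample channel and with the random slide block, 4 and 0 without the filter, 2 and 0 with the fixed slide block, 5 and 7 with the replicate block and 6 and 3 from the series matrix, and 4 and 0 or 4 and 2 when 1 of 7 arrays was left out. Probes called alike at 0.5 mM had 4 and 3 with only the compared arrays.

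Leaving out 1 array gave ranges of 289 to 816 and 127 to 494 for standard control and mismatch against phenol red. They were 88 to 187 and 1126 to 2139 for morpholino 1 against mismatch at 0.5 and 1 mM, 539 to 883 and 399 to 801 for morpholino 2 and both morpholinos at 0.5 mM, 9 to 43, 0 to 95, 0 to 6 and 1494 to 3429 between doses of standard control, mismatch, morpholino 1 and morpholino 2, 321 to 692 for the interaction and 499 to 777 called alike at 1 mM. Signal over background, 3.04 to 6.02 per array in Cy3, limits what dim probes can show, and 16176 probes were too dim to test.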

Other observations

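The tests between control oligonucleotides at doses other than 2 mM, those of the slide, reference channel, GC content and dose for that pattern, the agreement across doses and the counts of splits were chosen only after the results they bear on were seen.

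The standard control and the mismatch oligonucleotide gave different profiles at all 3 doses. They differed in 124 probes at 0.5 mM, 259 at 1 mM and 584 at 2 mM, and of the 259 probes called at 1 mM 98.8% and 100% had the same sign at 0.5 and 2 mM. The 140 probes lower with the standard control at 1 mM had medians of -0.29, -0.46 and -0.59 in its 3 doses, 0.17 in phenol red, 0.21 to 0.26 in the mismatch groups and 0.05 to 0.24 in the traf6 morpholino groups. LOLS13524 belonged to this set (adjusted p 1.47e-05 at 1 mM), with 1, 0 and 0 of 5 standard control arrays well above background at the 3 doses. The other 119 probes had medians of 0.11 to 0.17 with the standard control, -0.05 in phenol red and -0.47 to -0.28 with the mismatch. Of the traf6 calls, 640 of 5980 at 2 mM were also called between the control oligonucleotides over doses, where independent lists would share 380.2, although both lists draw on the 2 mM control arrays.

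These 259 probes read as a score per array gave 0.22 ± 0.05, 0.33 ± 0.06 and 0.37 ± 0.03 (SD, n = 5) in the standard control groups and -0.12 ± 0.04 (n = 5) in phenol red, while the mismatch groups had means of -0.27, -0.38 and -0.29, below phenol red at 0.5 and 2 mM (exact p 0.0238 and 0.0159, adjusted 0.0264 and 0.0199). The values argue against the slide, since at least 95.9% of probes called at 2 mM without a slide's arrays kept their direction within it, and against the reference channel, which moved by -0.0144 at the median where the ratio moved by 0.65. GC content is unlikely as the whole cause, because 95.9% of the calls kept their direction once the GC trend was taken off. The score rose from 0.5 to 2 mM of the standard control by 0.144 (all 5 arrays above the highest at 0.5 mM, exact permutation p 0.00794, adjusted 0.0113 over 10 tests), while the mismatch score changed by -0.02 (exact p 0.675). An action of the standard control oligonucleotide itself is a candidate explanation for the 140 lower probes, as a hypothesis whose probes came from the 1 mM arrays and whose scores came from the other doses of the same experiment.

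Agreement between the traf6 morpholinos was highest in 1 of 9 pairings of doses. The effects of morpholino 1 at 1 mM and morpholino 2 at 2 mM correlated at r = 0.512 across probes, with 1336 probes called alike where independent lists would share 276.9 and 56 called in opposite directions. At equal doses of 0.5, 1 and 2 mM r was 0.219, 0.363 and 0.211. The other 5 pairings across doses gave r between -0.00244 (morpholino 1 at 2 mM, morpholino 2 at 0.5 mM) and 0.234 (morpholino 1 at 0.5 mM, morpholino 2 at 1 mM). With the mismatch arrays of 1 mM as the control of morpholino 1 at 2 mM the correlation was 0.387. Mismatch against phenol red and morpholino 2 against the standard control, which share no array, correlated at 0.206. The differences between these correlations were not tested, and probes are not independent replicates.

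The first principal component held 16.7% of the variance, of which groups accounted for 68.5%, and the second 10.5%, of which slides accounted for 57.5% and replicate numbers for 42.7%. The Cy5 reference alone, tested in the same way with limma, gave between 0 and 24 called probes per comparison, with 24 for morpholino 1 against morpholino 2 and 600 at an unadjusted p under 0.05 for mismatch against standard control, whose count was 0. Probes that overlap in sequence without being identical (1306 pairs) had changes that correlated at 0.972 in both morpholinos against both controls at 2 mM, and all 309 pairs with the first called had the same direction.

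Other splits of the arrays into groups of the real sizes were counted, 100 per result and all 35 for morpholino 1 against mismatch at 0.5 mM. Many of the highest other splits were the real split with 1 array moved or exchanged. Their counts can thus hold part of a real difference. Chance cannot be excluded for mismatch against phenol red, where 11 of 100 splits, the real one included, called as many as its 283 probes. The highest other split there called 1206, several times the real count, and sets phenol red replicates 1 to 4 with 1 mismatch array against the rest, which points to a structure of the samples around phenol red replicate 5. Nor can it be excluded for the mismatch between doses, with 6 of 100 splits, a real count of 14 and a highest other of 126 that parts mismatch 2 mM replicate 1 and the 0.5 mM arrays from the rest.

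For the 21 other results only the real split, 1 of those counted, reached its own value. By this count chance is left open for morpholino 1 against mismatch at 0.5 mM and for the doses of morpholino 1 and of the standard control. For the other comparisons among the 21 it is less likely, but not excluded. Counts of probes called alike are not included in this. Without 1 array, some of these comparisons also fell below their highest other split, among them the interaction (321 and 434). Splits were made only with all arrays. For probes called alike the splits cannot test agreement, since the highest at 2 mM, 47, lay below the 267 expected of independent lists. Against phenol red the real and highest other counts were 474 and 233 (standard control), 2406 and 2071 (morpholino 1) and 9037 and 4539 (morpholino 2). They were 183 and 0, 2112 and 1136, and 2087 and 781 for morpholino 1 against mismatch at 0.5, 1 and 2 mM, and 3075 and 760, and 6667 and 2754 for morpholino 2 against the standard control at 1 and 2 mM. Both morpholinos at 2 mM gave 5980 and 1523, mismatch against standard control 584 and 463, doses of the standard control 29 and 10 (9 without replicate 5 at 0.5 mM), doses of morpholino 1 5 and 3 (a count that fell to 0 without replicate 1 or 2 at 0.5 mM, with 1441 and 933 unadjusted), the interaction 509 and 434 (321 to 692 leaving out 1 array, for which no splits were made), and probes called alike 27 and 1, 761 and 0, and 900 and 47. The limma counts of 0 came with up to 2851 probes at an unadjusted p under 0.05 for morpholino 1 at 0.5 mM, where the real split had fewer (2362), and with up to 641 alike at 1 mM.

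Where replicate numbers paired the arrays, the real split was set beside those that also part every pair. Morpholino 2 against the standard control at 0.5 mM gave 843, against 252 at most among 13 such splits and 541 among the rest. Both morpholinos at 0.5 mM gave 703, against 1 at most among 6 and 536 among the rest, the latter with replicates 1 and 5 against 2, 3 and 4. Both morpholinos at 1 mM gave 4545, against a limma count of 0 among 2 (up to 908 unadjusted) and 1125 among the rest. Morpholino 1 against morpholino 2 gave 5383, against 953 among 14 and 1634 among the rest. Doses of morpholino 2 gave 3288, against 110 among 12 and 2210 among the rest.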
